A study of Homo sapiens with 25 samples.

How the data were processed

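Transcript levels were measured on 25 Affymetrix expression arrays from 3 human cell lines, before and after addition of the EGFR kinase inhibitor erlotinib at 10 µM. The lines were the breast cancer lines BT20 and MDA-MB-453 and a line labelled only MCF. The deposited values are log2 GCRMA values per probe set, and per the submitters' processing notes they were made with GCRMA 2.20.0 in R 2.11.1. GCRMA subtracts a background that depends on probe sequence, normalizes the arrays to each other and summarises the probes of each probe set. The labels place the arrays in 2 parts, 19 arrays of BT20 and MDA-MB-453 in Part 1 and 6 arrays of MCF in Part 2. The 75th percentile of the values was 7.65 to 7.81 on the arrays of Part 1 and 7.27 to 7.32 on those of Part 2, so levels were compared within a part, and the parts were compared only through changes measured within each. For arrays, their number limits the precision. The labels do not state whether the replicates of a group were separate cultures, so each p-value measures the spread between these samples.

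The values were used as deposited, in R 4.3.3. Of the 54613 probe sets in the table, 41091 carried exactly 1 gene symbol, 1801 carried several and 11721 had none in the annotation used. A gene was represented by the probe set with 1 symbol and the highest mean over the 25 arrays, which gave 19775 genes. Genes with a log2 value above 4 on at least 3 arrays were tested, 12643 in number. A linear model with 8 group means, 1 per line and time point, was fitted to all 25 arrays with limma 3.58.1, which left 17 residual degrees of freedom, and moderated statistics were taken from its empirical Bayes step. The comparisons were 30 min, 6 h and 24 h with 0 min in BT20, 24 h with 6 h in BT20, 24 h with 0 min in MDA-MB-453 and in MCF, and the differences of the 24 h change between BT20 and each of the other lines. A gene was called when its two-sided p, adjusted by the method of Benjamini and Hochberg over the 12643 genes, was under 0.05. The levels of BT20 and MDA-MB-453 at 0 min were compared for 3 gene lists alone. Changes are differences of group means in log2 units, and the error after ± is the standard error of the fit unless SD is written.

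The comparisons, the filter, the probe set choice, 23 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The lists were tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over 23 lists and 8 comparisons together, and repeated with an estimated correlation and with fry, which asks whether the genes of a list move on balance in 1 direction. Counts of list members are given over all genes tested and, where stated, adjusted over the list alone. The genes named in a comparison are the 10 with the largest rise and the 10 with the largest fall among called genes that had a mean of at least 6 in the higher group and no overlap between the arrays of the groups. Up to 4 members of each list described, those with the smallest p, are named as well. The following 13 genes are named in every case: EGFR, ERBB2, ERBB3, DUSP6, SPRY4, EGR1, CCND1, MYC, CASP8, BID, CFLAR, BCL2L11 and CDKN1A. For the differences between lines the condition on overlap was dropped. Some genes fixed beforehand are not reported here.

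The model was tested on simulated data in which 200 of the 12643 genes were changed and each line kept its own residual spread. In the fit to all 25 arrays it recovered 64 to 86% of the genes changed by 1 log2 unit, and false calls made up 12.3% of the calls for BT20 at 30 min, 5.77% at 6 h, 8.75% at 24 h, 11.2% for 24 h with 6 h, 14.6% for MDA-MB-453 and 77.5% for MCF. In fits to the arrays of the line alone false calls made up 3.66 to 5.99% of the calls, and recovery at 1 log2 unit was 16% for MCF and 64 to 86% for the others. The MCF counts are therefore given from both fits. The simulated values held no batch and no correlation between genes, so these shares leave out false calls from either source. The shares also depend on the 200 genes changed. For MCF the simulation gave 702 calls, 544 of them false, more than the 404 calls in the data. Its 77.5% is therefore the share in the simulation and not an estimate for the data.

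One array of BT20 at 0 min, replicate 4, correlated more with the 6 h arrays than with the other 0 min arrays. A fit with a batch term for that array and the 6 h arrays was added after this was seen; in it the 6 h change is measured against replicate 4 alone and the other BT20 changes against replicates 1 to 3. A fit with a covariate for the spread of the MCF and MDA-MB-453 arrays was also added after the data were seen. Further fits were made with no filter, a filter at 6, the mean of a gene's probe sets, every probe set tested, a trended and robust empirical Bayes step, array weights, quantile normalization repeated, centring each array on its median, a replicate block, and with fits to the lines compared alone, replicate 4 as the only control, and leaving out each array in turn. The median change over all genes tested was between -0.02 and 0.05 in every comparison, so no shift was subtracted. A planned test of RNA quality from 3 prime and 5 prime control probe sets was not run, because the table holds no control probe sets. Genes with no name in the annotation were not named.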

Results

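The series holds 25 arrays in 8 groups. BT20, a breast cancer line with high EGFR and without ERBB2 amplification, was sampled before erlotinib (0 min, 4 arrays) and 30 min, 6 h and 24 h after it (3 arrays each). MDA-MB-453, a line with high ERBB2, was sampled at 0 min and 24 h (3 arrays each), and so was the line labelled MCF (3 arrays each). No group was kept for 24 h without drug, so each comparison over time holds the drug and the time in culture together. Between 43.1 and 45.6% of probe sets lay above a log2 value of 4 on each array. Where a group mean lay below 4, the level used for testing, the size of a difference is inexact, and the genes concerned are named. The comparisons ask which transcripts changed with time after EGFR inhibition and whether the change at 24 h differed between the lines.

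**Figure D1:**
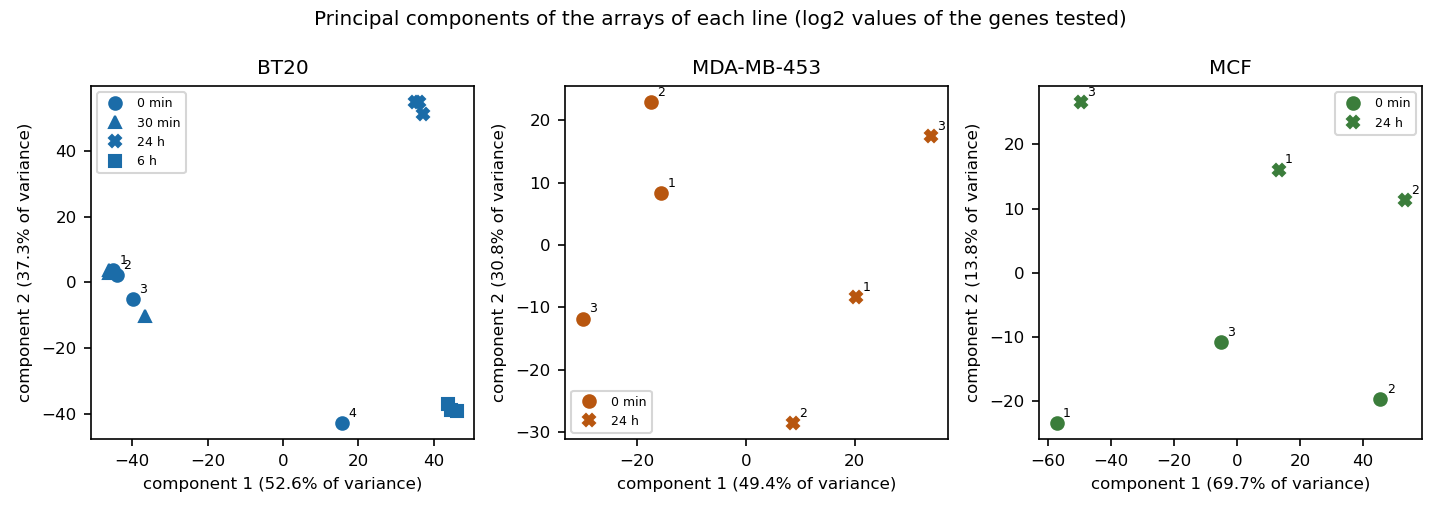
Principal components of the arrays of each line, from the log2 values of the genes tested; each point is an array, the axes give the share of variance, and the digits at the points of the 0 min groups, and of the 24 h groups of MDA-MB-453 and MCF, are replicate numbers. In BT20 replicate 4 of the 0 min group lay nearest the 6 h arrays, and in MCF the first component (69.7% of variance) did not separate 24 h from 0 min.

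Before treatment BT20 and MDA-MB-453 differed in the receptors and ligands of the ErbB family. EGFR, the target of erlotinib, had a mean log2 value of 12.38 in BT20 and 3.53 in MDA-MB-453 (difference 8.85 ± 0.23, n = 4 and 3, adjusted p = 1.88e-18). The EGFR ligands TGFA and EREG were higher in BT20 by 7.05 ± 0.23 and 9.39 ± 0.33, whereas the receptor ERBB4 was lower by -5.57 ± 0.19. ERBB2 was lower in BT20 by -2.92 ± 0.28 and ERBB3 by -1.72 ± 0.09. Of 13 measured members of the ErbB list, 5 were higher in BT20 and 6 in MDA-MB-453 (5 and 7 adjusted over the list alone). Of 11 basal epithelial markers, 10 were higher in BT20 and none in MDA-MB-453 (10 adjusted over the list alone), among them the keratin KRT5 by 9.51 ± 0.17, and ID4 by 5.43 ± 0.17. Of 19 luminal epithelial markers, 11 were higher in MDA-MB-453 and 6 in BT20, the same counts as adjusted over the list alone. AGR2 was lower in BT20 by -10.91 ± 0.13, CA12 by -9.74 ± 0.16 and PIP by -7.74 ± 0.22, while the estrogen receptor ESR1 was higher in BT20 by 6.05 ± 0.15. The lower mean lay below 4 for EGFR, EREG, ERBB4, KRT5, ID4, AGR2, CA12, PIP and ESR1, so the sizes of these differences are inexact. The MCF line, not compared in level with the others, had mean log2 values of 3.52 for EGFR, 12.47 for ESR1 and 13.5 for the estrogen-induced gene TFF1.

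At 30 min few BT20 transcripts were called. In the simulated data this comparison recovered 64% of the genes changed by 1 log2 unit and 20% of those changed by 0.5. Changes of that size may therefore have been missed. ZFP36, an early response gene whose product destabilises mRNA, fell by 1.38 ± 0.21 (n = 3 and 4, adjusted p = 0.0263), and it was the only gene that met the naming rule. The second of the 2 genes called, the long noncoding RNA MIR205HG, fell by 1.02 ± 0.16 (adjusted p = 0.0288) and is named after its values were seen. Of 21 transcripts that follow output of the kinase ERK, none was called over all genes, and 4 fell adjusted over the list alone: the cytokine LIF (-1.07 ± 0.24), the ERK pathway inhibitor SPRY2 (-0.79 ± 0.19), IER3 (-0.45 ± 0.14) and the ERK phosphatase DUSP6 (-0.62 ± 0.19). Of 21 immediate early genes 1 fell, and 2 fell adjusted over the list alone, ZFP36 and JUN (-0.44 ± 0.10). EGR1 differed by -0.80 ± 0.27 without passing (adjusted p = 1.00 over all genes, 0.0525 over the list alone). With all 4 controls MYC differed by -1.06 ± 0.60 and CASP8 by -0.37 ± 0.29, and the others of the always named genes by less than these (EGFR by 0.15, ERBB2 by 0.22, ERBB3 by 0.03, SPRY4 by -0.18, CCND1 by 0.02, BID by 0.03, CFLAR by -0.09, BCL2L11 by -0.09 and CDKN1A by -0.06). With the batch term, which leaves replicates 1 to 3 as the controls, MYC differed by -0.29 and CASP8 by -0.05. In that fit CDKN1A (-0.44) and BCL2L11 (-0.31) differed by more than CASP8, and none of these genes was called. Against replicate 4 of the 0 min group alone the sign turned for BCL2L11 (0.57) and CDKN1A (1.08).

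As whole lists at 30 min, the ERK output list (camera adjusted p = 0.000656), the immediate early list (6.89e-05), the G1/S and replication list (0.0171) and the mitosis list (0.000288) passed the test downwards. None passed with an estimated correlation (adjusted p = 0.140, 0.194, 0.0688 and 0.208 with an estimated correlation, in that order). The lysosome list (adjusted p = 0.0207, and 0.349 with an estimated correlation) and the blood cell markers, of which 2 were measured (adjusted p = 0.0235, and 0.147 with an estimated correlation), passed upwards with the preset correlation. With the batch term, which leaves replicates 1 to 3 as the controls, neither did (camera adjusted p = 0.848 and 0.374). The lists that passed downwards still passed with the batch term and the preset correlation. The limma fit called 2 genes at 30 min and left 337 with an unadjusted p under 0.05. That is a smaller share of the 12643 genes than the 0.05 that unchanged genes would give. With the batch term 1 gene, ZFP36, was called (-1.10 ± 0.13, adjusted p = 0.00162). A fit to the BT20 arrays alone called 1 gene, MIR205HG, and not ZFP36. The count was 0 without any 1 of the 30 min replicates 1, 2 or 3, and 1 without replicate 1 or replicate 4 of the 0 min group.

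By 6 h the transcripts that follow ERK output had fallen in BT20. DUSP6 fell by 5.58 ± 0.19 (from 9.19 to 3.61, n = 4 and 3, adjusted p = 5.79e-14) and SPRY4, an inhibitor of the same pathway, fell by 5.12 ± 0.17 (adjusted p = 4.40e-14). FOSL1, a subunit of the AP-1 transcription factor, fell by 6.42 ± 0.33, and CCND1, the gene for cyclin D1, fell by 1.26 ± 0.12. The 2 CCND1 probe sets tested changed by -2.44 and -1.26. Replicate 4 of the 0 min group lay with the 6 h arrays (r across genes, which are not independent replicates, of 0.994 to 0.996, against 0.983 to 0.985 with the other 0 min arrays), so each 6 h value is also given against replicate 4 alone, from the fit with a batch term. Against replicate 4 the changes were -5.81 ± 0.29 for DUSP6, -5.31 ± 0.25 for SPRY4, -5.40 ± 0.41 for FOSL1 and -1.26 ± 0.19 for CCND1. The 6 h means of DUSP6 (3.61) and SPRY4 (2.13) lay below 4, so the sizes of their falls are inexact. Of 21 measured members of the ERK output list, 19 fell and none rose (19 adjusted over the list alone), with a median change of -1.38, and against replicate 4 the count was 18 and the median -1.58. The list passed with an estimated correlation as well (adjusted p = 0.000907).

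The stress response and FOXO lists rose at 6 h. Of 26 genes of the amino acid and endoplasmic reticulum stress response, 17 rose and 1 fell (17 and 1 adjusted over the list alone; 11 rose against replicate 4), with an adjusted p of 0.000412 with an estimated correlation. DDIT4, an inhibitor of mTORC1, rose by 3.77 ± 0.21, the glutathione-degrading enzyme CHAC1 by 3.55 ± 0.31, VLDLR by 2.10 ± 0.19 and HERPUD1 by 1.22 ± 0.09; against replicate 4 they rose by 3.06, 3.46, 1.66 and 1.27. Of 22 transcripts that rise with FOXO activity when PI3K signalling is low, 13 rose and 2 fell (14 and 2 adjusted over the list alone; 7 rose against replicate 4), with an adjusted p of 0.00291 with an estimated correlation. CCNG2 rose by 2.75 ± 0.22, TSC22D3 by 2.52 ± 0.27, KLF9 by 2.55 ± 0.32 and KLHL24 by 3.86 ± 0.45, against 1.84, 2.10, 1.17 and 1.75 over replicate 4. The receptor ERBB3 rose by 0.67 ± 0.09 and by 0.64 ± 0.13 against replicate 4 (adjusted p = 0.00992). The EGFR ligand HBEGF fell by 2.77 ± 0.21 and changed by -2.40 against replicate 4. EGFR itself differed by -0.47 ± 0.23 (adjusted p = 0.115) and ERBB2 by -0.17 ± 0.28 (adjusted p = 0.657).

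Among the largest changes at 6 h, the mitochondrial folate enzyme ALDH1L2 rose by 4.23 ± 0.17, the transcription factor MKX by 3.82 ± 0.22, the pyruvate dehydrogenase kinase PDK4 by 3.68 ± 0.47, YPEL2 by 3.62 ± 0.30, POU2F3 by 3.71 ± 0.45 and LINC00662 by 3.97 ± 0.54. All 6 were also called against replicate 4, with rises of 3.74, 3.89, 1.54, 2.66, 1.67 and 1.52. The focal adhesion gene TNS4 fell by 5.30 ± 0.22, LINC01127 by 4.82 ± 0.29, MYEOV by 3.89 ± 0.20, PADI1 by 3.49 ± 0.40, MFSD2A from 7.03 to 3.73 and MARCHF4 by 3.27 ± 0.31, and all 6 were called against replicate 4 (-4.60, -3.72, -3.62, -1.65, -2.70 and -1.98). For ALDH1L2, MKX, PDK4 and MFSD2A the lower mean lay below 4, as it did for TMEM171. VHL (3.46 ± 0.67) and TMEM171 (-3.56 ± 0.52) were called only with the pooled controls, and against replicate 4 their values were 0.39 (adjusted p = 0.941) and -1.21 (adjusted p = 0.120). The BH3-only gene BCL2L11 rose by 0.54 ± 0.17 and 2.30-fold against replicate 4 (adjusted p = 0.000122). CASP8, the initiator caspase of death receptors, was called with the pooled controls (0.89 ± 0.29, adjusted p = 0.0215) but its value against replicate 4 was -0.08 (adjusted p = 0.999). CDKN1A likewise changed by -1.09 ± 0.26 with the pooled controls and by 0.05 against replicate 4. MYC (0.87 ± 0.60, adjusted p = 0.272), EGR1 (-0.36 ± 0.27, adjusted p = 0.304), BID (-0.35 ± 0.36, adjusted p = 0.479) and CFLAR (0.04 ± 0.22, adjusted p = 0.912) did not pass.

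With the pooled controls 4 further lists passed at 6 h with the preset correlation but not with an estimated one. Fewer of their members were called against replicate 4, as was so for the FOXO and stress response lists. Fewer calls there can also come from the lower precision of a single control array. The median of the stress response list was 0.66 both with the pooled controls and against replicate 4. Of 30 mitosis genes 17 rose and 1 fell (18 and 1 adjusted over the list alone; none against replicate 4), with adjusted p = 0.199 with an estimated correlation, and against replicate 4 the median was 0.21 (adjusted p = 0.265 with an estimated correlation). HMMR (1.01 ± 0.16) and NEK2 (0.71 ± 0.12) had the smallest p. Of 25 MYC target and ribosome biogenesis genes 13 fell (13 adjusted over the list alone; none against replicate 4), with adjusted p = 0.0707 with an estimated correlation, while against replicate 4 the median was -0.39 (adjusted p = 0.0276 with an estimated correlation). PES1 and BYSL fell by 1.38 ± 0.23 and 1.97 ± 0.34. Of 12 NF-kB targets 5 fell (5 adjusted over the list alone; 1 against replicate 4), with adjusted p = 0.118 with an estimated correlation, while against replicate 4 the median was -0.32 (adjusted p = 0.0405 with an estimated correlation). Of 24 ribosomal protein genes 8 fell (none adjusted over the list alone or against replicate 4), with adjusted p = 0.475 with an estimated correlation, and 0.458 against replicate 4. In total 4827 genes were called at 6 h, 2726 up and 2101 down (859 and 760 by at least 2-fold). With the batch term 292 were called, 139 up and 153 down, of which 254 were among the 4827 with the same direction, and 498 of the 4827 had the opposite sign.

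At 24 h the ERK output list had fallen in BT20 almost throughout. DUSP6 fell by 5.93 ± 0.19 (from 9.19 to 3.27; n = 4 and 3, adjusted p = 5.11e-15), SPRY4 by 4.76 ± 0.17, the receptor EPHA4 by 4.58 ± 0.20 and the transcription factor ETV4 by 2.66 ± 0.13. The 24 h means of DUSP6 and SPRY4 (2.49) lay below 4, so the sizes of both falls are inexact. Of 21 measured members, 20 fell and none rose (21 adjusted over the list alone), with a median change of -2.33 and adjusted p = 0.000269 with an estimated correlation. CCND1 fell by 1.14 ± 0.12 and MYC by 2.42 ± 0.60 (adjusted p = 0.00357; -1.65 ± 0.44 with the batch term). The 2 CCND1 probe sets tested changed by -2.87 and -1.14. EGFR differed by -0.54 ± 0.23 (adjusted p = 0.0841), while ERBB2 rose by 1.31 ± 0.28 (adjusted p = 0.000859) and ERBB3 by 0.75 ± 0.09 (adjusted p = 1.56e-06). All 8 EGFR probe sets tested had a lower mean at 24 h, with changes of -0.99 to -0.22. EGR1 fell by 0.80 ± 0.27 (adjusted p = 0.0261), and the batch term ended that call (-0.52, adjusted p = 0.0869).

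Genes of DNA replication and of ribosome biogenesis fell at 24 h. Of 31 G1/S and replication genes 21 fell and none rose (22 adjusted over the list alone), with a median of -0.57 and adjusted p = 0.000269 with an estimated correlation. MCM10, which acts at replication forks, fell by 1.14 ± 0.14, the origin licensing factor CDC6 by 1.26 ± 0.16, GINS3 by 0.65 ± 0.08 and DSCC1 by 0.79 ± 0.10. Of 25 MYC target and ribosome biogenesis genes 18 fell and none rose (20 adjusted over the list alone), with a median of -0.89 and adjusted p = 0.0063 with an estimated correlation. ODC1, the first enzyme of polyamine synthesis, fell by 1.25 ± 0.10 and MRTO4, a ribosome assembly factor, by 1.75 ± 0.20. Of 30 mitosis genes 7 rose and none fell (7 adjusted over the list alone), with CDC25C up by 1.40 ± 0.24, but the list did not pass (adjusted p = 0.0989), although it did with fry (adjusted p = 0.00563) and with the batch term (adjusted p = 0.0301). With an estimated correlation it passed neither without the batch term (adjusted p = 0.634) nor with it (adjusted p = 0.394). No member of the ribosomal protein list (24 genes) or of the respiratory chain list (26 genes) was called in either direction, also adjusted over the list alone.

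The stress response and FOXO lists were up at 24 h as well. Of 26 stress response genes 17 rose and none fell (17 adjusted over the list alone), with adjusted p = 0.000753 with an estimated correlation. DDIT4 rose by 4.17 ± 0.21, CHAC1 by 4.01 ± 0.31, VLDLR by 2.83 ± 0.19 and the asparagine synthetase gene ASNS by 2.54 ± 0.19. Of 22 FOXO-linked transcripts 12 rose and 2 fell (13 and 2 adjusted over the list alone), with adjusted p = 0.0081 with an estimated correlation, and 0.0579 with that in a fit to the BT20 arrays alone, where it did not pass. TSC22D3 rose by 4.03 ± 0.27, CCNG2, which slows the cell cycle, by 2.33 ± 0.22, YPEL3 by 2.22 ± 0.19 and BCL6 by 1.39 ± 0.14. Of 31 interferon-stimulated genes 15 rose and 2 fell (16 and 2 adjusted over the list alone), led by PARP9 (2.16 ± 0.16), UBE2L6 (1.98 ± 0.23), IRF1 (1.75 ± 0.19) and IRF9 (1.55 ± 0.16). That list passed with the preset correlation (adjusted p = 0.000624), with fry and with the batch term (adjusted p = 0.00298), but not with an estimated correlation (adjusted p = 0.132). Of 16 cholesterol synthesis genes 7 rose and none fell (7 adjusted over the list alone; adjusted p = 0.0207, and 0.0556 with an estimated correlation, or 0.0367 with that and the batch term), among them SREBF2 by 1.95 ± 0.23 and INSIG1 by 1.28 ± 0.19. Of 25 lysosome and autophagy genes 9 rose and none fell (10 adjusted over the list alone; adjusted p = 0.0298, and 0.398 with an estimated correlation), among them ULK1 by 1.83 ± 0.23 and WIPI1 2.83-fold. With the batch term 6 lysosome genes rose and 1 fell, and the list did not pass (adjusted p = 0.178).

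Some genes of cell death changed at 24 h. The BH3-only genes BMF, HRK and BCL2L11, whose products oppose BCL2, rose by 4.27 ± 0.22, 2.39 ± 0.40 and 0.96 ± 0.17, and BCL2 fell by 2.25 ± 0.17 (from 5.45 to 3.19). The lower means of BMF and BCL2 lay below 4. Of 18 measured genes of the BCL2 family list 4 rose and 2 fell, the same counts as adjusted over the list alone, and the list did not pass with camera (adjusted p = 0.618) but did with fry (adjusted p = 4.13e-05). In the death receptor list 3 of 14 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.888 for the list). The TRAIL receptor gene TNFRSF10A fell by 1.77 ± 0.14 and TNFRSF10B by 0.36 ± 0.08, whereas CASP10 rose by 2.46 ± 0.34 and CASP6 by 0.67 ± 0.14. CASP8 differed by -0.05 ± 0.29 (adjusted p = 0.923), BID by -0.28 ± 0.36 (adjusted p = 0.617) and CFLAR by -0.02 ± 0.22 (adjusted p = 0.957). For CFLAR the mean of its probe sets gave a rise of 0.44 (adjusted p = 0.0224). CDKN1A fell by 0.74 ± 0.26 (adjusted p = 0.0353) with the pooled controls, and its value against replicate 4 alone was 0.39 (adjusted p = 0.188).

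The lists of ErbB family members, DNA repair and p53 targets held called genes in both directions at 24 h without passing with camera. Of 13 ErbB members 2 rose and 5 fell (2 and 7 adjusted over the list alone; adjusted p = 0.119 for the list, and 5.11e-05 with fry), and the ligands HBEGF, EREG and TGFA fell by 3.69 ± 0.21, 2.45 ± 0.33 and 1.07 ± 0.23, HBEGF to 3.65, below 4. Of 33 DNA repair genes 4 rose and 3 fell (3 and 2 adjusted over the list alone; adjusted p = 0.539 for the list), with the damage checkpoint kinases CHEK1 down by -0.80 ± 0.12 and ATM up by 0.83 ± 0.18. Of 22 p53 targets 4 rose and 6 fell, also adjusted over the list alone (adjusted p = 0.852 for the list). TP53INP1 rose by 3.38 ± 0.22 and SESN2 by 2.58 ± 0.28, and AEN fell by 2.78 ± 0.32.

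Among the largest changes at 24 h, the long noncoding RNA LINC01133 rose from 2.46 to 9.76 (adjusted p = 7.97e-18). The immune checkpoint ligand gene VTCN1 rose by 5.94 ± 0.23, HCAR3 by 5.39 ± 0.14, the selenium carrier gene SELENOP by 5.37 ± 0.24, PELI2 by 5.20 ± 0.19 and ALDH1L2 by 5.04 ± 0.17. YPEL2, ZSCAN31 and POU2AF3 rose by 4.51 ± 0.30, 4.33 ± 0.24 and 4.31 ± 0.20. HSD3B1, a steroid hormone dehydrogenase, fell by 7.07 ± 0.15, LINC01127 by 6.49 ± 0.29, the hyaluronan-degrading gene CEMIP by 6.12 ± 0.37, FOSL1 by 5.98 ± 0.33 and ARNT2 by 5.89 ± 0.22. COL15A1, TNS4, MGAM and the receptor tyrosine kinase AXL fell by 5.39 ± 0.16, 5.12 ± 0.22, 5.10 ± 0.17 and 5.07 ± 0.16. Means below 4 make these sizes inexact for LINC01133, VTCN1, HCAR3, PELI2, ALDH1L2 and POU2AF3 at 0 min and for LINC01127, CEMIP, ARNT2, MGAM and AXL at 24 h. In total 4149 genes were called, 2387 up and 1762 down (1082 and 688 by at least 2-fold). With the batch term, which leaves replicates 1 to 3 as the controls, 4641 were called, and 3802 genes were called in both with the same direction. Against replicate 4 alone 2384 of the 4149 were still called in the same direction and 181 changed sign.

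**Figure D2:**
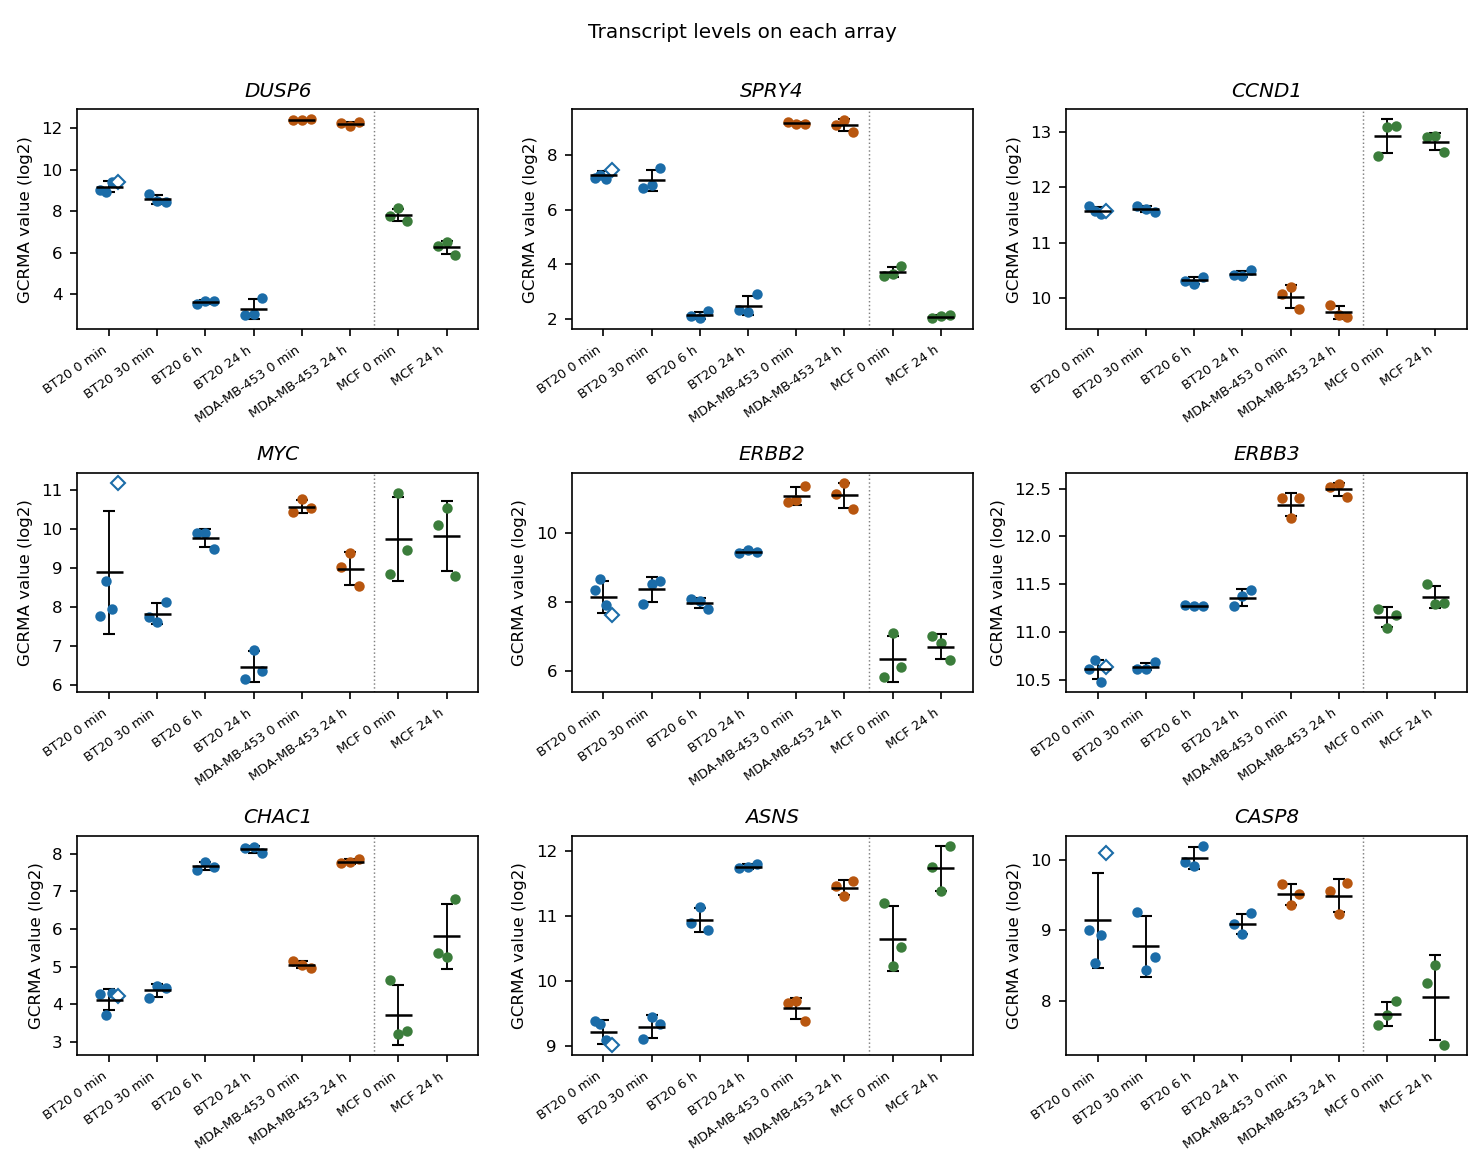
Log2 GCRMA value of 9 transcripts on each array; points are arrays, horizontal lines and bars are the group mean and SD, the open diamond is BT20 0 min replicate 4, and the dotted line separates the parts of the series, whose levels are not compared. DUSP6 lay between 8.93 and 9.42 on the BT20 arrays at 0 min and between 2.96 and 3.81 at 24 h, and between 12.1 and 12.4 on all 6 MDA-MB-453 arrays.

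Between 6 h and 24 h in BT20 the replication genes fell and ERK output stayed low. Of 31 G1/S genes 18 fell and none rose (18 adjusted over the list alone; 4 with the batch term), with adjusted p = 0.0019 with an estimated correlation; CDC6 fell by 1.91 ± 0.17 and MCM10 by 1.46 ± 0.15. DUSP6 differed by -0.34 ± 0.21 (adjusted p = 0.197) and SPRY4 by 0.35 ± 0.18 (adjusted p = 0.129), with both means of each below 4. LINC01133 rose by 5.48 ± 0.17, VTCN1 by 5.42 ± 0.24, SELENOP by 4.69 ± 0.26, the protease gene TMPRSS4 by 4.29 ± 0.27 and the cornified envelope gene IVL by 4.13 ± 0.24. COL15A1 fell by 5.15 ± 0.17, AXL by 4.73 ± 0.17, MGAM by 4.37 ± 0.18, CEMIP by 4.28 ± 0.39 and the cytokine receptor gene IL7R by 4.03 ± 0.17. The 6 h mean of VTCN1 and the 24 h means of AXL, MGAM, CEMIP and IL7R lay below 4. Of 31 interferon-stimulated genes 16 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.132 with an estimated correlation), led by IRF1 (1.98 ± 0.20) and PARP9 (1.52 ± 0.17). Of 25 lysosome genes 15 rose, also adjusted over the list alone (1 with the batch term; adjusted p = 0.208 with an estimated correlation). Of 21 ERK output genes 9 fell and 2 rose (9 and 2 adjusted over the list alone; adjusted p = 0.234 with an estimated correlation), and of 25 MYC targets 7 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.303 with an estimated correlation). BMF rose by 3.62 ± 0.23 and ERBB2 by 1.48 ± 0.30, the latter not called with the batch term (0.80, adjusted p = 0.387). EGFR (-0.06), ERBB3 (0.09), EGR1 (-0.43), CCND1 (0.12), BID (0.06), CFLAR (-0.06), BCL2L11 (0.43) and CDKN1A (0.34) did not pass. Of these, CDKN1A was called with the opposite sign with the batch term (-1.17, adjusted p = 0.00479), and CFLAR with the mean of its probe sets (0.49, adjusted p = 0.0166).

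The 6 h arrays lay near replicate 4 on the second principal component (-39.2 to -37.0, against -42.9) but not on the first (43.6 to 46.0, against 15.7). Some of the largest changes from 6 h to 24 h were smaller, absent or reversed with the batch term. With the batch term MEX3D (-5.25 ± 1.09, with a 24 h mean below 4) changed to 0.89, VHL (-4.13 ± 0.71) to -0.04, SLC35D1 (-4.11 ± 0.73) to 0.37, CLSPN (-3.84 ± 0.48) to -1.13 and MYC (-3.29 ± 0.65) to -0.23. CASP8 likewise changed from -0.94 ± 0.31 to 0.35. In total 5272 genes were called, 2707 up and 2565 down; with the batch term 1456 were called, of which 1015 were among the 5272 with the same direction.

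Genes called at both 6 h and 24 h in BT20 numbered 970 in the same direction upwards and 690 downwards, with 376 in opposite directions. Independent draws would give 515 and 293. Both changes were taken against the same 0 min arrays, and 20 simulations of unchanged groups against these controls gave a mean correlation across genes of 0.43 and no shared calls, where the data gave a correlation of 0.41. The simulated spread was independent between genes and held no batch. It therefore cannot tell how many shared calls come from replicate 4 lying apart from the other controls. The covariance of the changes was 0.236 in the data and 0.0287 in the simulations. With the 4 controls divided into pairs, 1 pair for each time point, 1036 to 1121 genes were shared in direction and 23 to 884 were opposite. With replicate 4 as the control at 6 h and replicates 1 to 3 at 24 h, 120 were shared upwards and 127 downwards with 8 opposite, where independent draws would give 29.6 and 23.6.

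In MDA-MB-453 the change of DUSP6, SPRY4 and CCND1 after 24 h of erlotinib did not pass the test. DUSP6 differed by -0.19 ± 0.21 (12.43 to 12.24, n = 3 and 3, adjusted p = 0.821), SPRY4 by -0.09 ± 0.18 (adjusted p = 0.942) and CCND1 by -0.29 ± 0.13 (adjusted p = 0.287). The DUSP6 level lay near the 99th percentile of the values, 12.6 on each MDA-MB-453 array. The 3 DUSP6 probe sets tested changed by -0.76 to -0.08. EGFR lay at 3.53 at 0 min and 3.57 at 24 h, and ERBB2 (11.07 at 0 min) differed by 0.01 ± 0.30 (adjusted p = 0.997). None of 21 ERK output genes was called, also adjusted over the list alone, and although the list passed with the preset correlation (median -0.19, adjusted p = 0.00375) it did not with an estimated one (adjusted p = 0.208 with an estimated correlation). EGR1 differed by -0.95 ± 0.29 (adjusted p = 0.0554) and MYC by -1.59 ± 0.65 (adjusted p = 0.191); in the fit with the batch term, which leaves the MDA-MB-453 estimates as they are and lowers the residual spread, MYC (adjusted p = 0.0276) and EGR1 (adjusted p = 0.012) passed.

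The stress response list rose in MDA-MB-453. Of 26 genes 8 rose and none fell (15 adjusted over the list alone), with adjusted p = 5.54e-05 with an estimated correlation. CHAC1 rose by 2.75 ± 0.33, ASNS by 1.85 ± 0.20, VLDLR by 1.69 ± 0.20 and the cystine transporter gene SLC7A11 2.83-fold. Of 22 FOXO-linked transcripts 3 rose and 1 fell (9 and 1 adjusted over the list alone), with adjusted p = 0.0063 with an estimated correlation, but 0.158 with that in a fit to the MDA-MB-453 arrays alone. The insulin receptor gene INSR rose by 0.64 ± 0.15 and the ubiquitin ligase gene FBXO32 fell by 1.86 ± 0.27. Of 25 MYC target and ribosome biogenesis genes 5 fell and none rose (7 adjusted over the list alone), with adjusted p = 0.003 with an estimated correlation. In the fit to the MDA-MB-453 arrays alone 17 fell adjusted over the list alone, with camera adjusted p = 0.0323 with an estimated correlation. MRTO4 fell by 1.22 ± 0.21, UTP20 by 1.33 ± 0.27 and ODC1 by 0.69 ± 0.10. None of 31 G1/S genes was called, also adjusted over the list alone, while the list passed downwards (median -0.12, adjusted p = 0.0472 with an estimated correlation, and 0.063 with that and the batch term; fry adjusted p = 0.00305). In the fit to the MDA-MB-453 arrays alone it did not pass with an estimated correlation (adjusted p = 0.126). The immediate early list (1 of 21 rose; 1 rose and 2 fell adjusted over the list alone) passed downwards with the preset correlation (adjusted p = 0.564 with an estimated correlation), and the lysosome list (2 of 25 rose; 4 adjusted over the list alone) upwards (adjusted p = 0.347 with an estimated correlation).

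The largest rises in MDA-MB-453 included FAXDC2 by 4.79 ± 0.24, the calcium-binding protein gene S100P by 4.15 ± 0.11, PAQR5 by 3.15 ± 0.25, TMEM178A by 2.71 ± 0.32, CREB3L1, a transcription factor of the endoplasmic reticulum, by 2.66 ± 0.24, ADHFE1 by 2.65 ± 0.23 and STC2 by 2.59 ± 0.27. S100A8 fell by 4.18 ± 0.37, DOCK2 by 3.56 ± 0.17, BBOX1 by 2.13 ± 0.16, LINC01208 by 1.91 ± 0.17, PRDM1 by 1.81 ± 0.13 and the heme oxygenase gene HMOX1 by 1.70 ± 0.23. One mean lay below 4 for FAXDC2, TMEM178A, S100A8, DOCK2, PMAIP1 and KLHDC1. Among death genes the BH3-only gene PMAIP1 rose by 1.79 ± 0.23 and TNFSF10, the gene for the death ligand TRAIL, 2.82-fold. BCL2L11 differed by 0.52 ± 0.18 (adjusted p = 0.105), CASP8 by -0.02 ± 0.31 (adjusted p = 0.994) and BID by -0.52 ± 0.39 (adjusted p = 0.628). ERBB3 (0.16), CFLAR (-0.28) and CDKN1A (0.04) did not pass either. The 6 BCL2L11 probe sets tested changed by -0.17 to 0.52, and only 2 of them in the direction of the value given. In total 730 genes were called, 534 up and 196 down (237 and 54 by at least 2-fold). Without 1 array of the 6 the count was 494 to 663, of which 70.7 to 77.4% rose. The fit to the MDA-MB-453 arrays alone called 1049 genes, 715 up and 334 down, of which 572 were among the 730. KLHDC1 (2.66 ± 0.25) lost its change with the mean of its probe sets (-0.02).

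In MCF ERK output genes fell at 24 h. ETV5, a transcription factor induced through ERK, fell by 2.61 ± 0.12 (from 9.99 to 7.38, n = 3 and 3), and DUSP6 fell by 1.56 ± 0.21 (adjusted p = 0.000104). SPRY4 was called as well, but its means of 3.72 and 2.08 both lay below 4. Of 21 ERK output genes 8 fell and none rose (13 adjusted over the list alone; 8 adjusted over the list alone in a fit to the MCF arrays only), with a median of -0.59 and adjusted p = 0.0019 with an estimated correlation. EGFR was called (adjusted p = 0.0348) with means of 3.52 and 2.55, both below that level, so no change is read from it, and CCND1 differed by -0.10 ± 0.13 (adjusted p = 0.876). ERBB2 (0.36), ERBB3 (0.21), EGR1 (0.07), MYC (0.07), CASP8 (0.23), BID (-0.78), CFLAR (0.07), BCL2L11 (0.04) and CDKN1A (-0.22) did not pass. In a fit to the MCF arrays alone DUSP6 (adjusted p = 0.198), SPRY4 (adjusted p = 0.0744) and EGFR (adjusted p = 0.885) did not pass.

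Replication genes fell and stress response genes rose in MCF. Of 31 G1/S genes 11 fell and none rose (19 adjusted over the list alone; 3 in the fit to the MCF arrays only), with adjusted p = 7.27e-06 with an estimated correlation; MCM10 fell by 1.00 ± 0.15, MCM3 by 0.87 ± 0.15 and CDC6 by 0.84 ± 0.17. Of 26 stress response genes 7 rose and none fell (11 adjusted over the list alone; 2 in the fit to the MCF arrays only), with adjusted p = 7.27e-06 with an estimated correlation; CHAC1 rose by 2.09 ± 0.33 from a mean below 4, SLC7A11 by 1.16 ± 0.12, ASNS by 1.08 ± 0.20 and HERPUD1 by 0.70 ± 0.10. Of 12 NF-kB targets 4 fell and none rose (5 adjusted over the list alone; 4 in the fit to the MCF arrays only), with adjusted p = 0.0063 with an estimated correlation; TNFAIP2 fell by 0.85 ± 0.14 and CXCL8 by 1.31 ± 0.31. The FOXO, cholesterol, mitosis, lysosome and luminal lists passed upwards with the preset correlation but not with an estimated one. Of their members 1, 0, 1, 0 and 1 rose (1, 0, 1, 0 and 1 adjusted over the list alone), and the values were adjusted p = 0.0501, 0.0688, 0.535, 0.412 and 0.152 with an estimated correlation. With fry the FOXO, cholesterol and luminal lists passed (adjusted p = 0.00234, 0.00296 and 0.0251), and with the batch term the FOXO list passed with an estimated correlation as well (adjusted p = 0.0175).

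CYP1A1, a target of the aryl hydrocarbon receptor, rose by 3.82 ± 0.33 in MCF, the retinol metabolism gene DHRS3 by 2.01 ± 0.24, CPS1 by 1.54 ± 0.30, MT1F by 1.38 ± 0.18, SELENOP by 1.38 ± 0.26, CBS by 1.26 ± 0.16 and HOXC4 by 1.17 ± 0.16. SPRR1B fell by 3.39 ± 0.35 to a mean below 4, NT5E by 2.01 ± 0.14, DIO2 by 2.00 ± 0.12, S100A8 by 1.96 ± 0.37, the glutamate transporter gene SLC1A3 by 1.93 ± 0.30, OLFML3 by 1.80 ± 0.15 and ANXA1 by 1.74 ± 0.32. In total 404 genes were called in MCF, 148 up and 256 down (40 and 99 by at least 2-fold). Without 1 array of the 6 it was 280 to 583, of which 32.8 to 44.6% rose. The MCF arrays spread more within groups than those of the other lines. A fit to these 6 arrays alone called 1 gene, ETV5 (adjusted p = 0.0334, with 0.0681 for CYP1A1), and left 736 with an unadjusted p under 0.05. On simulated data 77.5% of the MCF calls of the fit to all arrays were false, but the simulation did not match the count of calls in the data. In the fit to the MCF arrays alone the 4 lists passed with the preset correlation. With an estimated one the adjusted p was 0.035 for ERK output, 0.0209 for G1/S and for the stress response and 0.0848 for NF-kB targets, which did not pass.

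**Figure D3:**
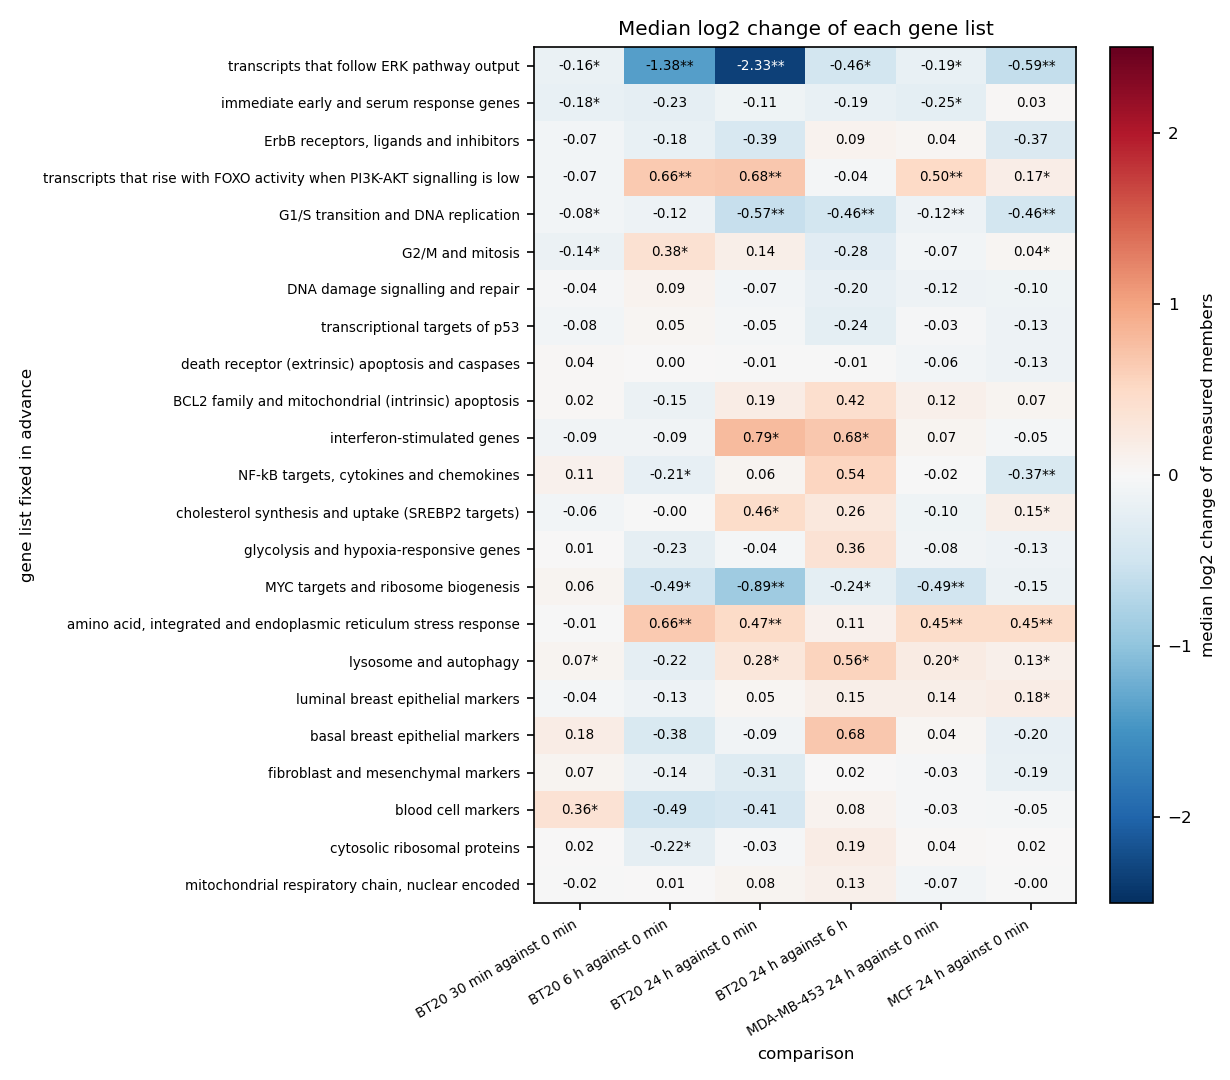
Median log2 change of the measured members of each gene list (vertical axis) in 6 comparisons (horizontal axis), from blue (lower) to red (higher); 1 asterisk marks an adjusted p under 0.05 with a preset correlation and 2 mark one that also holds with an estimated correlation. The ERK output list moved by -2.33 in BT20, -0.19 in MDA-MB-453 and -0.59 in MCF at 24 h, and the stress response list by 0.47, 0.45 and 0.45.

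The 24 h change differed between BT20 and MDA-MB-453 for 1872 genes, 972 more positive and 900 more negative in BT20 (706 and 575 by at least 2-fold). Of 21 ERK output genes 17 were more negative in BT20 and none more positive (18 adjusted over the list alone), with a median difference of -1.66 and adjusted p = 0.000269 with an estimated correlation. For single genes the difference was -5.74 ± 0.29 for DUSP6 (n = 4, 3, 3 and 3, adjusted p = 1.11e-11), -4.68 ± 0.25 for SPRY4, -4.45 ± 0.30 for EPHA4 and -0.86 ± 0.18 for CCND1. Of 31 G1/S genes 6 were more negative in BT20 (7 adjusted over the list alone; adjusted p = 0.00229 with an estimated correlation). Of 16 cholesterol synthesis genes 6 were more positive (7 adjusted over the list alone; adjusted p = 0.0063 with an estimated correlation), with IDI1 at 1.07 ± 0.20 and INSIG1 at 1.29 ± 0.27. ERBB3 rose more in BT20 by 0.59 ± 0.13 (adjusted p = 0.0036) and ERBB2 by 1.29 ± 0.40 (adjusted p = 0.0338; 0.0536 with the batch term). The stress response list did not pass the camera test of the difference (adjusted p = 0.167; fry adjusted p = 8.67e-06), nor did BCL2L11 (0.44 ± 0.25, adjusted p = 0.304) or MYC (-0.83 ± 0.88, adjusted p = 0.661). Nor did EGFR (-0.58), EGR1 (0.15), CASP8 (-0.03), BID (0.24), CFLAR (0.26) or CDKN1A (-0.78). The BCL2L11 probe set used had the highest change in both lines. The 6 BCL2L11 probe sets tested changed by 0.23 to 0.96 in BT20 and by -0.17 to 0.52 in MDA-MB-453. VTCN1 (6.01 ± 0.33), PELI2 (5.88 ± 0.27) and LINC01133 (5.43 ± 0.24) had the largest positive differences and HSD3B1 (-6.84 ± 0.22), CEMIP (-6.74 ± 0.53) and LINC01127 (-6.72 ± 0.43) the largest negative ones. Of these and of DUSP6 and SPRY4, all had a BT20 mean below 4 except HSD3B1, and HSD3B1, CEMIP and LINC01127 had MDA-MB-453 means below 4 at both times.

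Between BT20 and MCF the 24 h change differed for 1949 genes, 1248 more positive and 701 more negative in BT20 (860 and 432 by at least 2-fold). However, 9 of 100 divisions of the arrays called at least as many, so chance is not excluded for that count. Each line was divided separately, so a division can keep 1 line grouped as it was, and the share does not measure chance alone. Of 21 ERK output genes 16 were more negative in BT20 and 1 more positive (17 and 2 adjusted over the list alone), with adjusted p = 0.00154 with an estimated correlation; the difference was -4.74 ± 0.30 for EPHA4, -4.37 ± 0.29 for DUSP6 and -3.13 ± 0.25 for SPRY4. For SPRY4 both MCF means and the BT20 mean at 24 h lay below 4, so the size of that difference is not read. The 24 h mean of DUSP6 in BT20 also lay below 4. Of 22 FOXO-linked genes 8 were more positive and 1 more negative (10 and 1 adjusted over the list alone; adjusted p = 0.0377 with an estimated correlation, but 0.073 with that in the fit to the arrays of the lines compared), among them YPEL3 (2.05 ± 0.29) and BCL6 (1.33 ± 0.21). Of 25 MYC targets 8 were more negative (10 adjusted over the list alone; adjusted p = 0.0197 with an estimated correlation), among them WDR12 (-1.13 ± 0.16) and ODC1 (-1.09 ± 0.14). Of 31 interferon-stimulated genes 15 were more positive and 1 more negative (16 and 2 adjusted over the list alone), led by XAF1 at 4.62 ± 0.69, with adjusted p = 0.0601 with an estimated correlation. BCL2L11 rose more in BT20 by 0.92 ± 0.25 (adjusted p = 0.0137), ERBB3 by 0.54 ± 0.13 (adjusted p = 0.00757), and CCND1 differed by -1.05 ± 0.18. EGFR (0.43), ERBB2 (0.95), EGR1 (-0.87), MYC (-2.49), CASP8 (-0.28), BID (0.50), CFLAR (-0.09) and CDKN1A (-0.52) did not pass. The G1/S and stress response lists did not pass the camera test of the difference (adjusted p = 0.192 and 0.215) but did with fry (adjusted p = 0.0462 and 2.21e-07). The fit to the arrays of the lines compared kept 1644 of the 1949 genes.

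Genes called at 24 h were shared between lines beyond independent draws. BT20 and MDA-MB-453 shared 287 rising genes (101 by independent draws) and 109 falling ones (27.3), with 46 in opposite directions, and BT20 and MCF shared 89 (27.9) and 119 (35.7), with 30 opposite. In all 3 lines 34 genes rose (1.18 by independent draws) and 15 fell (0.553). The MCF calls in these counts are those of the fit to all arrays, and none of the 34 or the 15 was called in the fit to the MCF arrays alone. Of the genes already named here, ASNS, CHAC1, HERPUD1, CYP1A1, DHRS3 and ADHFE1 were among the 34, and CYP1A1 rose by 2.77 ± 0.31 in BT20 and 2.30 ± 0.33 in MDA-MB-453.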

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

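Of the tests below, those of a mislabelled array, of an axis shared by 2 lines and of ERK output as the source of the stress response were chosen after the result was seen. In BT20 at 0 min, 6 of 23 list means had 1 array apart from the other 3 by a test of the gap relative to the range. Replicate 4 had an immediate early mean of 8.414 (others 7.765 to 7.835), a mitosis mean of 10.95 (others 10.69 to 10.71), a basal mean of 8.148 (others 8.725 to 8.773), a mesenchymal mean of 5.61 (others 6.029 to 6.071) and a blood cell marker mean of 3.704 (others 4.576 to 4.62). Replicate 3 had a G1/S mean of 10.94 (others 11.02 to 11.03). About 1 in 20 groups would show such an array by chance. Of 33 other named genes 12 had such an array, replicate 4 in 10 of them, and of the 13 always named genes 0 had one. That 0 does not show that the always named genes were unaffected by replicate 4. Replicate 4 was the array farthest out for EGFR, SPRY4, EGR1, MYC, CASP8, BCL2L11 and CDKN1A, though below the cut of the test. Nearest the cut were EGR1, at 13.1 on replicate 4 (others 11.85 to 12.07), and CDKN1A, at 7.647 (others 8.933 to 9.289). For ERBB2, ERBB3, DUSP6, CCND1, BID and CFLAR another array was farthest out.

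Replicate 4 of the BT20 0 min group lay with the 6 h arrays. If it were a mislabelled 6 h array, the ERK output list would not differ between it and the 6 h arrays, but the median difference was -1.59 (bootstrap -2.11 to -1.33), which excludes that account. A shared batch of culture or array processing predicts that replicate 4 departs from the other controls in the direction in which 6 h departs from 24 h. The correlation across genes was 0.579 (0.56 to 0.598). Replicate 4 was already known to lie with the 6 h arrays, so such a correlation would arise from other causes too and does not test the batch. Batch and time cannot be told apart for the rest of the 6 h change. A difference at the level of probes predicts that probe sets of the same gene move apart, and the ratio of their correlation to that of the 24 h change was 0.543 (0.5 to 0.586), which leaves that account open.

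The MCF arrays spread along an axis that was not time and that held 80.2% of the variance within groups. A difference in proliferation predicts that the G1/S and mitosis lists slope along this axis. The larger of their median slopes was -0.0232 (bootstrap -0.087 to 0.0186). This argues against that account for the transcripts of these lists on these arrays, but does not exclude it for the cultures in general. The axis resembled the first axis within the MDA-MB-453 groups, with a correlation across genes of 0.498, so it was not particular to MCF. The probe set ratio was 0.496 (0.445 to 0.551), which leaves a technical difference at the level of probes open.

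The stress response list rose at 24 h in all 3 lines. As a consequence of lower ERK output it would rise less in MDA-MB-453, where ERK output genes were not called, and the ratio of the MDA-MB-453 rise to the BT20 rise was 0.958 (bootstrap 0.463 to 1.44), which leaves the account open. Gradual exhaustion of the medium would give a smaller rise at 6 h than at 24 h, and the ratio of 6 h to 24 h was 1.19 (0.418 to 2.33), which leaves that account open as well. Without an untreated group at 24 h these accounts cannot be told apart.

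The arrays of each comparison were also divided in other ways, in all possible ones for the changes over time and in 100, the real one among them, drawn at random for the differences between lines. For BT20 at 30 min 3 of 35 splits called at least as many genes as the real one (2 real, 540 at most otherwise), so the 30 min count is within what such splits give. At 6 h 2 of 35 did (4827 real, 6009 at most otherwise), and the higher count came from setting replicate 4 with the 6 h arrays, near which it lay. At 24 h 1 of 35 did, the real split itself (4149 real, 3533 at most otherwise). For 24 h with 6 h it was 1 of 10 (5272 real, 0 otherwise) and for MDA-MB-453 1 of 10 (730 real, 16 at most otherwise), and 10 splits are too few for a share under 0.05. For MCF it was 3 of 10 (404 real, 4680 at most otherwise), also too few, and the counts of the other splits point to structure among these arrays. For the difference between BT20 and MDA-MB-453 it was 2 of 100 (1872 real, 3766 at most otherwise, with the BT20 arrays grouped as they were) and for that between BT20 and MCF 9 of 100 (1949 real, 5466 at most otherwise), so the latter count is within what such splits give. In both differences each line was divided separately, so a split can keep 1 line as it was, and neither share measures chance alone.

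The 24 h change differed between BT20 and MDA-MB-453 for 1872 genes. The lists that differed with both correlations had median differences of -1.663 for ERK output, -0.3846 for G1/S and 0.695 for cholesterol synthesis, and 5 further lists passed with the preset correlation only. Of these 5, only the interferon list passed with an estimated correlation in the fit to the arrays of the lines compared (camera adjusted p = 0.0264). Among the always named genes the differences were 1.295 for ERBB2, 0.5929 for ERBB3, -5.742 for DUSP6, -4.679 for SPRY4 and -0.8583 for CCND1, and 19 other named genes passed. Between BT20 and MCF 1949 genes differed, the list medians were -1.408 for ERK output, 0.6156 for FOXO and -0.7266 for MYC targets, and 1 further list passed with the preset correlation only. The gene differences were 0.5409 for ERBB3, -4.366 for DUSP6, -3.129 for SPRY4, whose MCF means both lay below 4, -1.048 for CCND1 and 0.9171 for BCL2L11, and 20 other named genes passed. Of 5189 probe sets without exactly 1 gene name among 29774 tested, 1305 were called in BT20 at 24 h, 616 of them by at least 2-fold, and none of these enters the gene counts.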

How the results depend on the processing

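The batch term, the axis score and replicate 4 as the control of single genes were chosen after the data were seen. With every probe set tested the counts were 6 at 30 min, 9997 at 6 h, 8621 at 24 h, 11252 for 24 h with 6 h, 1450 in MDA-MB-453, 694 in MCF, and 3510 and 4016 for the differences of BT20 from MDA-MB-453 and from MCF. With array weights they were 134, 9301, 8067, 9170, 4390, 12037, 6018 and 8257 in that order, but the weights (0.0471 to 819) did not converge. A replicate block gave 1 at 30 min, 1110 in MDA-MB-453 and 626 in MCF; of 24 pairs of arrays with the same replicate number, over 8 group pairs, 5 had residuals correlated above 0.1, and for 7 the best match was the same number. The batch term gave 1 at 30 min, 292 at 6 h, 1456 for 24 h with 6 h and 612 in MCF. The axis score gave 1242 in MDA-MB-453, 1023 in MCF and 3126 for BT20 with MCF. The arrays of the line alone gave 1 at 30 min and 1 in MCF. Replicate 4 as the only control gave 2485 at 30 min and 246 at 6 h, a filter at 6 gave 1 at 30 min, centring on the median gave 0, and leaving out single arrays gave 0 to 3 at 30 min. Genes shared by 6 h and 24 h numbered 1660, and 1104, 1036, 1106, 1083 and 1071 with the controls divided, 545 at 2-fold or more, and 247 with replicate 4 for 6 h and replicates 1 to 3 for 24 h. Against replicate 4 alone the sign turned for BCL2L11 (0.57) and CDKN1A (1.08) at 30 min, CASP8 (-0.0773) and CDKN1A (0.0507) at 6 h, where the batch term gave the same values, and CDKN1A (0.39) at 24 h. From 6 h to 24 h the batch term turned MEX3D (0.89), SLC35D1 (0.37), CASP8 (0.35) and CDKN1A (-1.17). The mean of a gene's probe sets turned CFLAR at 24 h (0.44) and from 6 h (0.49) and KLHDC1 in MDA-MB-453 (-0.0217). Of 54 list results, 31 were weaker with an estimated correlation, 9 with fry and 8 with the batch term. The cause of these shifts was not tested, and the planned test of RNA quality was not run.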

Other observations

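Some markers of cell state changed in BT20 at 24 h. Of 10 mesenchymal genes 4 fell and none rose: the transcription factors SNAI2 (-1.87 ± 0.21) and ZEB1 (-0.71 ± 0.19), the actin-binding gene TAGLN (-1.87 ± 0.41) and the cadherin CDH2, whose means both lay below 4. The list did not pass with camera (adjusted p = 0.103) but did with the batch term (adjusted p = 0.0495; 0.323 with an estimated correlation) and with fry (adjusted p = 0.00343). Replicate 4 of the controls lay apart on the mesenchymal and basal means. Of 19 luminal genes 5 rose and 3 fell, with the epithelial factor ELF3 up by 1.94 ± 0.25 and the sodium channel subunit SCNN1A by 3.18 ± 0.58 (adjusted p = 0.716 for the list, and 0.0345 with fry). Of 11 basal genes 2 rose and 2 fell, with CRYAB up by 1.61 ± 0.19 and the integrin ITGB4 down by -1.39 ± 0.50. Of 27 glycolysis and hypoxia genes 4 rose and 7 fell, with the stress gene NDRG1 up by 1.00 ± 0.14 and the hexokinase gene HK2 down by -0.94 ± 0.14.

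Of the genes called in all 3 lines at 24 h, the following were chosen after their values were seen. The MCF calls are those of the fit to all arrays, and none of these genes was called in the fit to the MCF arrays alone. The stress regulator NUPR1 rose by 4.11 in BT20, 0.94 in MDA-MB-453 and 1.02 in MCF, and the stress transcription factor DDIT3 by 1.11, 1.10 and 0.88. The ribosome biogenesis gene TCOF1 changed by -1.35, -0.80 and -0.87, S100A2 by -1.79, -0.97 and -1.58, and the nucleotide synthesis gene CTPS1 by -0.61, -0.59 and -0.54. A mean lay below 4 for NUPR1 in MCF and for S100A2 in MDA-MB-453 and MCF.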
